A study of Mus musculus with 16 samples.

How the data were processed

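The deposited files hold, per the file headers, for each cytosine and strand the counts of all, methylated and unmethylated bisulfite calls, as whole numbers without normalization. They also hold, per the file headers, the methylated fraction, and this deposited fraction equalled methylated over total counts, within 0.000001, in every line of every file. Per the submitters' processing notes, the authors used CASAVA 1.8.2, Bismark 0.7.6 and SAMtools with the mm9 build; which step each tool did, the filters and the handling of duplicate reads are not given in the sources used here. Each file holds 1 library, with no pooling. The highest total at a cytosine was between 7887 and 8017 in every file, as if the read depth had been capped near that value. Per the labels, DNA was digested with TaqI, end-repaired and A-tailed with Klenow enzyme and unmethylated nucleotides, ligated to adapters, treated with bisulfite and amplified, with 20 cycles in the first round of PCR. Fragments of 200 to 500 bp were taken.

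Groups and replicate numbers come from the labels: 16 libraries in 8 groups, namely oocyte 1 and 2, sperm 1, wild-type female 1, 2 and 3, Tet3-deficient female 1 and 4, aphidicolin-treated female 2 and 3, wild-type male 2 and 3, Tet3-deficient male 1 and 3 and aphidicolin-treated male 1 and 2. Groups, tests and a first list of alternatives were fixed before the data were examined. The alternatives chosen after the data were seen were leaving out TaqI sites, a moderated linear model on tile levels, at most 130 calls per CpG, counting the wild-type male libraries as 1, leaving out 3 libraries, CpGs methylated in both gametes, and splitting non-CpG cytosines by the next base. The 3 libraries left out in that alternative were wild-type female 1, Tet3-deficient female 1 and Tet3-deficient male 1, which had the highest levels at CpGs methylated only in the other parent's gamete.

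Calls on the 2 strands of a CpG were summed. Autosomal CpG calls per library were 39558166 and 37893814 in oocytes 1 and 2, 37635573 in sperm, 25512540, 27241052 and 23147186 in wild-type female 1, 2 and 3, 27996687 and 22888418 in Tet3-deficient female 1 and 4, and 27087942 and 28755771 in aphidicolin-treated female 2 and 3. They were 31023808 and 29904915 in wild-type male 2 and 3, 30523799 and 34525751 in Tet3-deficient male 1 and 3, and 30330013 and 23549754 in aphidicolin-treated male 1 and 2. The libraries together covered 1471487 autosomal CpGs, of which 4.61% lay in TCGA on both strands. The sequence around a CpG was read from the files' own context columns. A CpG was left out as a TaqI site where it lay in TCGA, or in CGA seen on 1 strand only, which came to 37.3% of the CpGs.

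A mean level is the unweighted mean over autosomal CpGs with at least 5 calls in every library compared and in the gamete named. CpGs were called gamete-methylated at 70% or more and unmethylated under 20%. CpGs methylated only in 1 gamete were at 80% or more there and at 5% or less in the other. CpG density is the number of other CpGs seen within 50 bp on either side, in classes under 3, 3 to 6 and over 6. A CpG was in a repeat where the reference base was lower case in the files. Differences of group means were tested by exact permutation of library labels, two-sided. The smallest p is 0.1 for 2 against 3 libraries and 0.333 for 2 against 2. For both pronuclei together labels were permuted within each pronucleus, in 60 arrangements. With 1 sperm library its mean levels were not tested.

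Tiles are 100 bp wide, on the 19 autosomes, with at least 10 CpG calls in every library compared. Each tile was tested with a logistic model of methylated and unmethylated counts. The dispersion was taken from the 7 groups with more than 1 library, moderated across tiles as in limma's squeezeVar and not allowed below 1, with an F test and Benjamini-Hochberg adjustment. A tile was called at an adjusted p below 0.05 and a difference of at least 10 percentage points. A library standing alone, as for sperm, is assumed to vary as much as libraries of other groups. The effect of a treatment in male against female pronuclei was tested as an interaction in the same model. It was called at an adjusted p below 0.05 with no minimum difference. Larger or smaller in the male refers to the effect in percentage points, not on the logit scale. Alternatives included edgeR's likelihood ratio test on methylated and unmethylated counts with a library term, a dispersion from the compared groups only, calls thinned to the lowest library, tiles of 1000 bp, other thresholds, the 99.9th percentile of coverage as a limit, and leaving out each library in turn on the same tiles. Named tiles are the first 5 in each direction by absolute difference among called tiles whose library levels do not overlap between the groups; the text prints some of these, and a tile outside the rule is said to be named after its values were seen.

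The tile test was tested on simulated data with 200 changed tiles at the real depths, changed by 20, 40 or 80 points. The first setting assumed a within-group correlation of 0.3, a large spread that was not estimated from these libraries. Of 38848 tiles of Tet3-deficient against wild-type female pronuclei, 0 of 60, 0 of 70 and 7 of 70 changed tiles were recovered, with 6 false calls. Of 103950 tiles of aphidicolin-treated against wild-type male pronuclei, 0 of 60, 0 of 70 and 0 of 70 were recovered, with 0 false calls. With a correlation of 0.01, the same comparisons recovered 30 of 60, 67 of 70 and 70 of 70 with 14 false calls, and 8 of 60, 44 of 70 and 64 of 70 with 18 false calls. Among unchanged tiles at 5% to 95%, 11.4% and 7.11% had an unadjusted p below 0.05 at the higher correlation. Among all unchanged tiles the shares were 7.87% and 4.55%. A count of tiles at an unadjusted p below 0.05 therefore includes unchanged tiles and by itself shows no effect. A linear model on tile levels recovered 0, 2 and 22 with 68 false calls, and 3, 7 and 24 with 591 false calls, at the higher correlation. At the lower it recovered 27, 61 and 70 with 16 false calls, and 8, 37 and 61 with 94. The 80-point class and the lower correlation were added to the simulation after a first version with 20 and 40 points recovered almost no tile; the test was not altered.

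PCR reads without molecular identifiers are not independent molecules, and about 100 to 130 pronuclei entered a library, so the calls at a CpG can outnumber its molecules. The SD between libraries was used for that reason and no interval from call counts is given; such an interval would cover counting error only. The wild-type male libraries were compared before averaging. They differed by 1.91 times binomial sampling, more than sampling noise, and were kept as 2. Positions are those of the files, in mm9, counted from 1. Gene names were not used here, because the gene table at hand is on another build, and mitochondrial DNA was not analysed here. Chromosome X is described apart and chromosome Y is used only as a check of parental origin. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pyarrow 21.0.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and the package data.table at version 1.17.8.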

Results

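CpG methylation was measured by reduced representation bisulfite sequencing in mouse gametes and in the separated pronuclei of the zygote. Bisulfite leaves both 5-methylcytosine and 5-hydroxymethylcytosine unconverted, so a level given here counts the 2 marks together. The 16 libraries came from metaphase II oocytes (n = 2), sperm (1 library) and pronuclei isolated from zygotes. Female pronuclei, which carry the maternal genome, were wild type (n = 3), from eggs lacking Tet3 (n = 2), or from zygotes kept in aphidicolin (n = 2). Male pronuclei, which carry the paternal genome, came from the same 3 kinds of zygote (n = 2 each). Tet3 is the dioxygenase that oxidises 5-methylcytosine in the zygote, and here it was deleted in growing oocytes with Zp3-Cre. Aphidicolin, given at 0.2 µg/ml from sperm injection to isolation, inhibits DNA polymerases and so blocks pronuclear DNA replication. Per the labels, zygotes were collected 7.5 to 8 h after intracytoplasmic sperm injection, and about 100 to 130 pronuclei were pooled.

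Autosomal CpG calls per library ranged from 22888418 (Tet3-deficient female replicate 4) to 39558166 (oocyte replicate 1). CpGs with at least 5 calls ranged from 127459 in Tet3-deficient female replicate 4 to 745484 in sperm, with a median of 28 to 62 calls per such CpG. Mean levels below are unweighted means over autosomal CpGs with at least 5 calls in every library compared and in the gamete of that pronucleus. "Gamete-methylated" CpGs were at 70% or more in that gamete. CpGs in the TaqI recognition site, where the DNA was digested, read 95.7% to 98.3% methylated on average in every library. Levels are therefore also given without CpGs at TaqI sites, a choice made after the data were seen. Differences between groups were tested by exact permutation of libraries, two-sided, and 100-bp tiles by a limma-moderated quasi-binomial test. The labels do not say whether the libraries of a group came from separate collections of animals, so p-values measure the spread between these libraries, which may be partly technical.

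**Figure D1:**
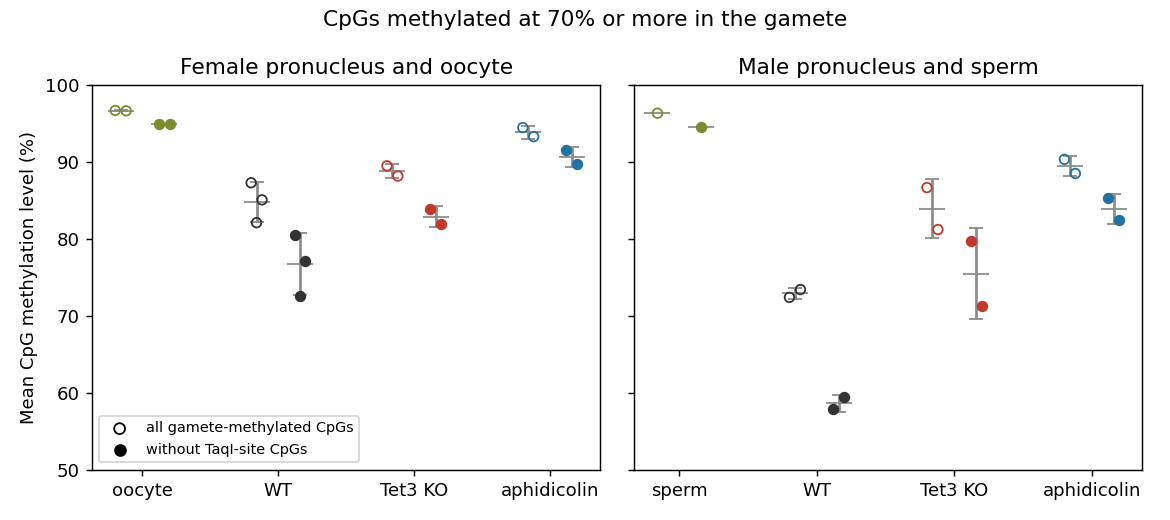
Mean methylation level (%) at gamete-methylated CpGs covered in all libraries of a pronucleus and its gamete, one point per library, with grey bars for the group mean and SD, for the female side (left) and the male side (right). Open circles include CpGs at TaqI sites and filled circles leave them out; wild-type male pronuclei have the lowest filled circles, at 57.9% and 59.4%.

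The first comparison followed the maternal genome from the egg into the zygote. Oocyte-methylated CpGs were lower in the female pronucleus than in the oocyte: they averaged 96.5% ± 0.00909 (SD, n = 2) in oocytes and 85.9% ± 2.77 (n = 3) in wild-type female pronuclei, over 48966 CpGs. Without TaqI sites the means were 94.6% and 77.7% ± 4.38, over 30683 CpGs. Choosing CpGs on the oocyte level raises the oocyte mean and shrinks its SD. Over all 116376 CpGs, with no such choice, the levels were 47.3% ± 0.255 and 42.5% ± 2.08. Each of the 3 pronucleus libraries lay below both oocyte libraries in all of these sets. The exact permutation test gave p = 0.1 for each, the smallest value that 2 against 3 libraries allow.

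Of 49890 tiles, 25 were called higher in oocytes and 0 lower by the limma-moderated test. Tiles with an unadjusted p below 0.05 numbered 6172 in the higher and 631 in the lower direction. Such counts, here and below, include unchanged tiles and by themselves show no effect. On chromosome 15 (98555901 to 98556000, mm9) the 2 oocyte libraries read 93.4% and 96.6% and the female pronuclei 20.7% ± 9.34 (adjusted p = 0.0341, 55 to 457 calls per library). A tile on chromosome 8 (34944801 to 34944900) read 99.1% ± 1.11 and 52.1% ± 10.8 (adjusted p = 0.0374). On chromosome 2 (55067201 to 55067300), within repeats, the values were 44.9% ± 6.15 and 0.356% ± 0.323 (adjusted p = 0.031). The count rested on single libraries. The limma-moderated test called 0 tiles without oocyte replicate 1 and 0 without oocyte replicate 2, with 4062 and 4411 tiles at an unadjusted p below 0.05. It called 9 without wild-type female replicate 2 and 106 without wild-type female replicate 1; edgeR called 2286 with all libraries. With the dispersion of the 2 groups compared only, or with calls thinned to the lowest library, the limma-moderated test called 0, with 6229 and 2811 tiles at an unadjusted p below 0.05.

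Oocytes also carry methylation outside CpG, which sperm largely lack. At 356134 cytosines followed by A, the level was 8.74% ± 0.127 in oocytes and 7.75% ± 1.40 in wild-type female pronuclei (exact permutation p = 0.5). Over all 1012769 CHG and CHH cytosines the levels were 3.97% ± 0.0615 and 3.54% ± 0.614 (exact permutation p = 0.6), a difference smaller than the SD of the pronuclei. Cytosines followed by C read 0.536% ± 0.00574 and 0.548% ± 0.0853. The difference over all of them, 0.427 points, was 0.105 without wild-type female replicate 3 and 0.716 without replicate 1. The CHH difference changed sign without wild-type female replicate 3, from 0.313 to -0.0469 points. Over 495292 cytosines covered in every library, the CA level was 0.789% in sperm and 0.960% ± 0.120 in wild-type male pronuclei. In the same set Tet3-deficient female replicate 4 read 11.5% and replicate 1 read 7.19%, against 6.73% ± 0.988 in wild-type and 8.50% ± 0.0139 in aphidicolin-treated female pronuclei. Replicate 4 also had the highest CC level, 0.878%, against 0.435% to 0.554% in the other 6 female libraries.

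**Figure D2:**
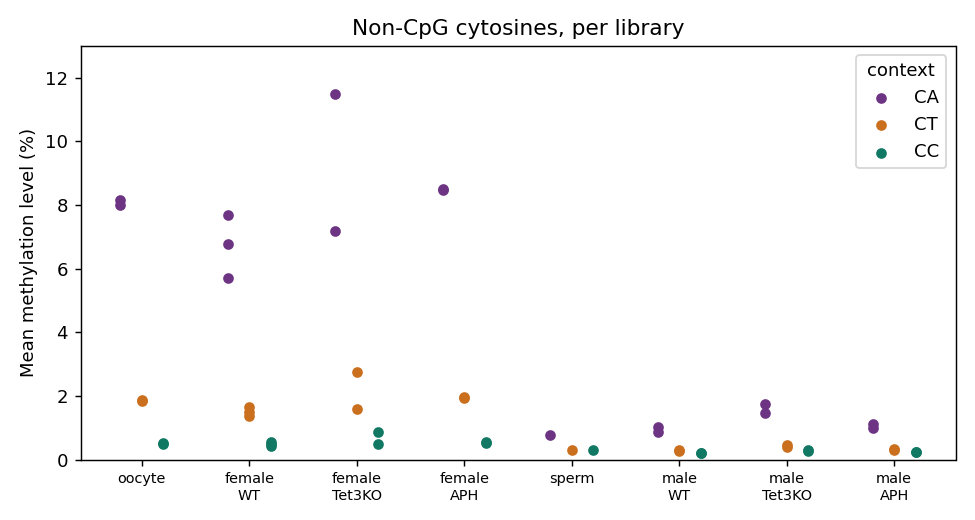
Mean methylation level (%) of cytosines followed by A (CA), T (CT) or C (CC), one point per library, over the 495292 non-CpG cytosines covered in every library. CA methylation stands above CT and CC in oocytes and female pronuclei, and is 0.789% in sperm.

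The paternal genome, followed from sperm to the male pronucleus, showed the larger difference. Sperm-methylated CpGs averaged 96.6% in sperm and 76.0% ± 0.642 (n = 2) in wild-type male pronuclei, over 223598 CpGs. Without TaqI sites the levels were 94.4% and 59.9% ± 1.08, a difference of 34.5 points. Over all 319795 CpGs, with no choice on the sperm level, they were 70.5% and 55.5% ± 0.397. The means were not tested, since 1 against 2 libraries allows no permutation p below 0.333. The 2 wild-type male libraries were also unusually alike. Their squared differences at partly methylated CpGs averaged 1.91 times binomial sampling, against 7.34 to 12.4 in the 8 other replicate pairs, so their SD may understate the spread of separate collections.

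Tiles gave the same direction: 1784 of 139815 were called higher in sperm and 0 lower, with 29533 higher and 264 lower at an unadjusted p below 0.05. By oocyte level, 709 of the called tiles were at 70% or more in oocytes and 918 under 20%, out of 50112 and 43710 tested tiles in these classes. On chromosome 3 (130823001 to 130823100) the level was 99.1% in sperm and 0% in both male libraries (adjusted p = 0.0497, 60 to 230 calls). A tile on chromosome 6 (38131301 to 38131400) read 99.6% in sperm and 3.45% ± 4.88 in male pronuclei (adjusted p = 0.0185). The count rested on the dispersion as well as on the calls, since the small spread between the 2 male libraries enters it. Without either male library the mean difference over all CpGs stayed at 14.7 to 15.2 points. With the 2 libraries counted as 1, a choice made after the data were seen, 51 tiles were called, and edgeR called 60318 with both. Counting the 2 as 1 keeps their pooled calls and takes their spread out of the dispersion, so the lower count reflects mainly the dispersion. With calls thinned to the lowest library 28 were called, and with the dispersion of the 2 groups compared only 49484.

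Loss of maternal Tet3 was compared with wild type first in the female pronucleus. The mean level was slightly higher without Tet3. Oocyte-methylated CpGs averaged 89.3% ± 0.918 (n = 2) in Tet3-deficient and 85.5% ± 2.41 (n = 3) in wild-type female pronuclei, over 36587 CpGs. Without TaqI sites the values were 82.8% ± 1.44 and 76.7% ± 3.89. Both Tet3-deficient libraries lay above all 3 wild-type libraries, but for oocyte-methylated CpGs another split gave as large a difference (exact permutation p = 0.2, smallest possible 0.1). Over all 84335 CpGs the levels were 45.4% ± 0.413 and 42.6% ± 1.54 (exact permutation p = 0.1). The difference at oocyte-methylated CpGs, 3.79 points, was 2.52 points without wild-type female replicate 3.

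Few tiles separated Tet3-deficient from wild-type female pronuclei: 26 of 38848 were called, 21 higher and 5 lower, with 3187 and 1105 at an unadjusted p below 0.05. In simulated data for this comparison, with the larger assumed spread, 7.87% of unchanged tiles had such a p. Of the 21 higher tiles 7 were at 70% or more in oocytes, 6 at 20% to 70% and 8 under 20%, out of 17072, 5224 and 14648 tested. On chromosome 13 (107182901 to 107183000) the level was 84.3% ± 3.17 without Tet3 and 1.33% ± 2.30 in wild type, against 21.6% in oocytes and 85.5% in sperm (adjusted p = 0.0144). A tile on chromosome 9 (5764201 to 5764300) read 55.0% ± 0.935 and 1.97% ± 2.02, against 2.01% in oocytes and 96.3% in sperm (adjusted p = 0.00542). Among the lower tiles, chromosome 17 (12611601 to 12611700) read 14.4% ± 1.03 and 58.3% ± 5.85 (adjusted p = 0.00573). The others lay on chromosome 16 (42985701 to 42985800, 23.0% and 77.4%) and chromosome 7 (35366901 to 35367000, 6.92% and 45.9%). The remaining 2, whose library levels overlapped and which were named after their values were seen, adjoin each other on chromosome 2 (128865001 to 128865200). They read 1.23% ± 1.12 and 22.9% ± 20.6, and 1.17% ± 1.15 and 23.3% ± 21.6. Without Tet3-deficient female replicate 4 the limma-moderated test called 0 tiles, with 2806 at an unadjusted p below 0.05, and without wild-type female replicate 2 it called 5. Tet3-deficient female replicate 1 and wild-type female replicate 1 also read highest at CpGs methylated only in sperm, 18.0% and 11.5%; without them and Tet3-deficient male replicate 1, 4 tiles were called. With the dispersion of the 2 groups compared only, the limma-moderated test called 0 tiles (3875 at an unadjusted p below 0.05); it called 2 with calls thinned to the lowest library, and edgeR called 25.

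In the male pronucleus, loss of maternal Tet3 went with a higher mean level. Sperm-methylated CpGs averaged 84.7% ± 3.54 (n = 2) without Tet3 and 74.3% ± 0.638 (n = 2) in wild type, over 160226 CpGs. Without TaqI sites they averaged 75.6% ± 5.64 and 59.0% ± 1.02, against 94.4% in sperm in the wild-type comparison above. Both Tet3-deficient libraries lay above both wild-type libraries, and the exact permutation test gave p = 0.333, the smallest that 2 against 2 allow. The difference at sperm-methylated CpGs, 10.4 points, was 7.87 points without Tet3-deficient male replicate 1. That library read 20.3% at CpGs methylated only in oocytes, the highest of the male pronuclei. In wild-type libraries 36.7% and 33.2% of sperm-methylated CpGs outside TaqI sites were at or below 50%, against 9.96% and 19.2% without Tet3.

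Of 105024 tiles, 1019 were called in the male pronucleus, 992 higher without Tet3 and 27 lower, with 13391 and 1190 at an unadjusted p below 0.05. Of the higher tiles 935 were at 70% or more in sperm, a class of 80470 tested tiles, and the median difference was 48.0 points. On chromosome 12 (86027601 to 86027700) the level was 97.2% ± 3.95 without Tet3 and 0% in both wild-type libraries, and the adjoining tile (86027701 to 86027800) read 98.4% ± 2.30 and 0.806% ± 1.14 (adjusted p = 0.0367 and 0.03). The chromosome 6 tile named above for sperm (38131301 to 38131400) read 99.7% ± 0.416 without Tet3 (adjusted p = 0.00593); both comparisons use the same wild-type male libraries. Lower tiles included chromosome 8 (4917901 to 4918000) at 5.20% ± 0.248 and 82.7% ± 7.39 (adjusted p = 0.0197). The limma-moderated test called 1 tile without wild-type male replicate 2, 5 without replicate 3 and 237 without Tet3-deficient male replicate 1. With the wild-type male libraries counted as 1 it called 295 tiles, and without Tet3-deficient male replicate 1 and the 2 female libraries named above, whose spread also enters the test, it called 2. With the dispersion of the 2 groups compared only it called 0 (18863 at an unadjusted p below 0.05) and with calls thinned to the lowest library 85, while edgeR called 9200.

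Taking both pronuclei, the mean excess without Tet3 at gamete-methylated CpGs was 7.08 points, 3.79 in the female and 10.4 in the male pronucleus (exact permutation within pronucleus, p = 0.0333 of 60 arrangements, two-sided). Without TaqI sites it was 11.3 points (exact permutation p = 0.0333). Without wild-type female replicate 1, 2 or 3 the excess was 7.14, 7.64 or 6.44 points, in a design of 36 arrangements that allows no exact permutation p below 0.0556. Without Tet3-deficient female replicate 4 or 1 it was 6.75 or 7.40 points (exact permutation p = 0.0833). With CpGs taken from 1 call, the excess was 5.65 points (exact permutation p = 0.0667), and without the 3 libraries doubted above 6.22 points (exact permutation p = 0.111 of 9 arrangements). Male and female pronuclei may come from the same zygotes, so they may not be independent. Tested on the logit scale with no minimum difference, the effect itself differed between pronuclei at 62 of 35452 tiles. In percentage points it was larger in the male at 47 and smaller at 15. The count was higher without TaqI sites, as given with the processing below. Without Tet3-deficient male replicate 1 the numbers were 63 larger and 47 smaller, and without the 3 libraries doubted above 58 and 50. A linear model (limma) on the percentage-point scale called 215, 176 larger and 39 smaller. The logit count was 35 without wild-type female replicate 2 and 11 without Tet3-deficient female replicate 4. It was 140 and 131 without wild-type male replicates 2 and 3, and 110 and 173 without Tet3-deficient male replicates 1 and 3.

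Aphidicolin-treated pronuclei were compared with wild-type ones next. Replication was not measured here, so a difference is not shown to be the part of the loss that needs it. In the female pronucleus oocyte-methylated CpGs averaged 93.6% ± 0.856 (n = 2) with aphidicolin and 85.2% ± 2.94 (n = 3) without, over 40473 CpGs. Without TaqI sites the levels were 90.3% ± 1.31 and 77.6% ± 4.43. Both treated libraries lay above all 3 untreated libraries (exact permutation p = 0.1, the smallest possible). Tiles followed the same direction: 978 of 45354 were called, 951 higher with aphidicolin and 27 lower, with 7219 and 972 at an unadjusted p below 0.05. Of the higher tiles 737 were at 70% or more in oocytes, 114 at 20% to 70% and 95 under 20%, out of 19188, 6894 and 17979 tested. On chromosome 1 (95376601 to 95376700) the level was 100% in both treated libraries and 12.3% ± 11.7 in untreated ones (adjusted p = 0.0425, 18 to 408 calls). A tile on chromosome 3 (81300701 to 81300800) read 97.3% ± 0.0655 and 18.2% ± 17.6 (adjusted p = 0.0306). Lower tiles included chromosome 10 (26199901 to 26200000) at 0.794% ± 1.12 and 66.0% ± 11.1 (adjusted p = 0.0273). The count was 1662 without aphidicolin-treated female replicate 2, 2 without replicate 3 and 594 without wild-type female replicate 3. Without the libraries doubted above 616 tiles were called. With the dispersion of the 2 groups compared only, the limma-moderated test called 0 tiles (5806 at an unadjusted p below 0.05). It called 4 with calls thinned to the lowest library and 13 with at most 130 calls per CpG, while edgeR called 1171.

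In the male pronucleus the difference with aphidicolin was larger. Sperm-methylated CpGs averaged 89.9% ± 1.17 (n = 2) with aphidicolin and 74.1% ± 0.730 (n = 2) without, over 154396 CpGs. Without TaqI sites they averaged 84.1% ± 1.83 and 59.2% ± 1.15. Both treated libraries lay above both untreated ones (exact permutation p = 0.333, the smallest possible). Of 103950 tiles, 3623 were called, 3601 higher with aphidicolin and 22 lower, with 20673 and 718 at an unadjusted p below 0.05. The higher tiles were at 70% or more in sperm in 3389 cases, out of 79140 tested. By oocyte level, 1672 of them were at 70% or more and 1483 under 20%, out of 37827 and 35811. On chromosome 17 (71113201 to 71113300) both treated libraries read 100% and both untreated ones 0%, against 88.1% in oocytes and 97.2% in sperm (adjusted p = 0.0357, 48 to 138 calls). A tile on chromosome 4 (100753701 to 100753800) read 99.4% ± 0.852 and 0% (adjusted p = 0.0409). Among the lower tiles, chromosome 7 (24096601 to 24096700) read 26.3% ± 3.47 and 73.3% ± 3.85 (adjusted p = 0.0428). The limma-moderated test called 0 tiles without aphidicolin-treated male replicate 1, with 12171 at an unadjusted p below 0.05. It called 11 without wild-type male replicate 2, 81 without replicate 3, and 1121 with these 2 libraries counted as 1. With calls thinned to the lowest library it called 187, with the dispersion of the 2 groups compared only 6454, and edgeR called 16280.

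Across both pronuclei the mean excess with aphidicolin at gamete-methylated CpGs was 12.1 points (exact permutation within pronucleus, p = 0.0167, the smallest that 60 arrangements give). It was 8.40 points in the female and 15.8 in the male pronucleus, and 18.8 points in the mean without TaqI sites. Without wild-type female replicate 1, 2 or 3 the excess was 12.3, 12.7 or 11.3 points, in a design that allows no exact permutation p below 0.0556. Tested on the logit scale with no minimum difference, the effect differed between pronuclei at 61 of 39478 tiles. In percentage points it was larger in the male at 44 and smaller at 17. A linear model (limma) on percentage points called 1434, 1340 larger and 94 smaller. The logit count moved with every library. It was 39, 33 and 110 without wild-type female replicates 1, 2 and 3, and 200 and 14 without aphidicolin-treated female replicates 2 and 3. It was 200 and 170 without wild-type male replicates 2 and 3, and 96 and 123 without aphidicolin-treated male replicates 1 and 2.

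Set against each other, the 2 perturbations left different levels. In the female pronucleus oocyte-methylated CpGs averaged 89.8% ± 0.817 without Tet3 and 94.4% ± 0.757 with aphidicolin (n = 2 each, 37471 CpGs). In the male pronucleus sperm-methylated CpGs averaged 84.0% ± 3.79 and 89.5% ± 1.27 (n = 2 each, 130962 CpGs). Without TaqI sites the female values were 82.9% ± 1.34 and 90.6% ± 1.28 and the male values 75.5% ± 5.81 and 83.9% ± 1.94. Libraries of the 2 treatments did not overlap in either pronucleus (exact permutation p = 0.333 each, the smallest possible). The male difference of -5.48 points was -2.80 points without Tet3-deficient male replicate 3. When each library was averaged over its own CpGs, the female difference over all CpGs was 0.0529 points, against -2.30 over shared CpGs.

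In female pronuclei 195 of 40400 tiles were called between the 2 perturbations, 162 lower and 33 higher without Tet3, with 3957 and 1721 at an unadjusted p below 0.05. Of the 162 lower tiles 104 were at 70% or more in oocytes, a class of 17679 tested tiles, while 25 of the 33 higher tiles were under 20% there, a class of 14698. On chromosome 17 (87024201 to 87024300) the level was 4.33% ± 4.64 without Tet3 and 100% in both aphidicolin-treated libraries, as in oocytes (adjusted p = 0.0421). The chromosome 13 tile named above (107182901 to 107183000) read 84.3% ± 3.17 and 0.621% ± 0.878 (adjusted p = 0.0026). The count was 7 and 31 without Tet3-deficient female replicates 4 and 1, and 632 and 6 without aphidicolin-treated female replicates 2 and 3. In male pronuclei 70 of 88745 tiles were called, 60 lower and 10 higher without Tet3, with 7406 and 2036 at an unadjusted p below 0.05. On chromosome 6 (88706701 to 88706800) the level was 16.9% ± 4.22 without Tet3 and 99.3% ± 1.00 with aphidicolin (adjusted p = 0.0238). Adjoining tiles on chromosome 11 (69804901 to 69805100), methylated in oocytes and not in sperm, read 84.4% ± 3.66 and 77.5% ± 4.67 without Tet3 and 0% with aphidicolin. The male count was 502 and 4 without Tet3-deficient male replicates 1 and 3, and 18 and 275 without aphidicolin-treated male replicates 1 and 2. Without the libraries doubted above the counts were 28 in female and 137 in male pronuclei. With the dispersion of the 2 groups compared only, the limma-moderated test called 0 tiles in both (5100 and 5694 at an unadjusted p below 0.05); with thinned calls it called 3 and 8, while edgeR called 425 and 541.

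The parental pronuclei of wild-type zygotes had similar mean levels over all shared CpGs but differed where both gametes were methylated. At 40561 CpGs at 70% or more in both gametes, male pronuclei averaged 75.3% ± 0.243 (n = 2) and female pronuclei 86.9% ± 2.82 (n = 3). Without TaqI sites the levels were 59.4% ± 0.389 and 78.4% ± 4.64. Both male libraries lay below all 3 female libraries (exact permutation p = 0.1, the smallest possible). Over all 108249 CpGs the levels were 42.9% ± 0.422 and 41.7% ± 2.13, which overlapped (exact permutation p = 0.8). That difference, 1.11 points, was -0.0962 points without wild-type female replicate 3 and 1.92 points without replicate 1.

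Tiles differed widely between the parental pronuclei: 11894 of 49661 were called, 7814 higher and 4080 lower in the male. Of the higher tiles 6400 were under 20% in oocytes, out of 18818 tested. Of the lower tiles 3722 were at 70% or more in oocytes, out of 21382. By sperm level, 2568 of the lower tiles were at 70% or more and 1034 under 20%. The count thus includes differences already present between the gametes. With replicate numbers fitted as a block every call was lost, as given with the processing below. That fit also took the dispersion from these libraries only, with few residual degrees of freedom, so the loss cannot be put down to the block alone. On chromosome 15 (41496701 to 41496800) the level was 100% in both male libraries and 2.03% ± 3.52 in female ones, against 100% in sperm and 0% in oocytes (adjusted p = 0.00139). On chromosome 16 (5307101 to 5307200) it was 1.58% ± 0.727 and 99.7% ± 0.495, against 1.08% in sperm and 71.7% in oocytes (adjusted p = 7.89e-05). A tile on chromosome 1 (34021501 to 34021600), methylated in both gametes, read 0% in both male and 100% in all female libraries (adjusted p = 0.0493, 12 to 251 calls). The count was 5643 without wild-type male replicate 2 and 4998 without replicate 3, and 3740 with calls thinned to the lowest library.

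The gametes differed in mean level. Over 347989 CpGs it was 52.3% ± 0.491 (n = 2) in oocytes and 69.6% in sperm, and 40.3% ± 0.622 and 62.0% without TaqI sites. Of 154192 tiles, 34380 were called, 31706 lower and 2674 higher in oocytes. On chromosome 8 (81668901 to 81669000) both oocyte libraries read 0% and sperm 100% (adjusted p = 0.000188). On chromosome 9 (53619601 to 53619700) the values were 100% and 0% (adjusted p = 0.000353). The count was 21252 without oocyte replicate 1 and 21993 without oocyte replicate 2.

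Gamete-methylated CpGs were then split by the density of other CpGs within 50 bp, without TaqI sites and without further tests. Wild-type female pronuclei read 77.7% ± 4.16 at CpGs with under 3 neighbours, 76.3% ± 4.18 at 3 to 6 and 74.1% ± 6.25 at over 6. Tet3-deficient female pronuclei read 86.2% ± 0.864, 81.2% ± 1.60 and 75.3% ± 3.27 in the same classes, so their excess over wild type was within the SD at the densest CpGs. Aphidicolin-treated female pronuclei read 91.8% ± 1.51, 90.3% ± 1.16 and 86.3% ± 0.935. In wild-type and aphidicolin-treated male pronuclei the classes differed less than in the female ones. Wild type read 57.6% ± 1.48, 59.6% ± 0.730 and 59.5% ± 0.229, and aphidicolin-treated 83.7% ± 1.76, 84.1% ± 2.20 and 84.2% ± 2.05. Tet3-deficient male pronuclei fell with density, from 76.8% ± 5.88 through 74.3% ± 5.85 to 71.9% ± 6.66.

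**Figure D3:**
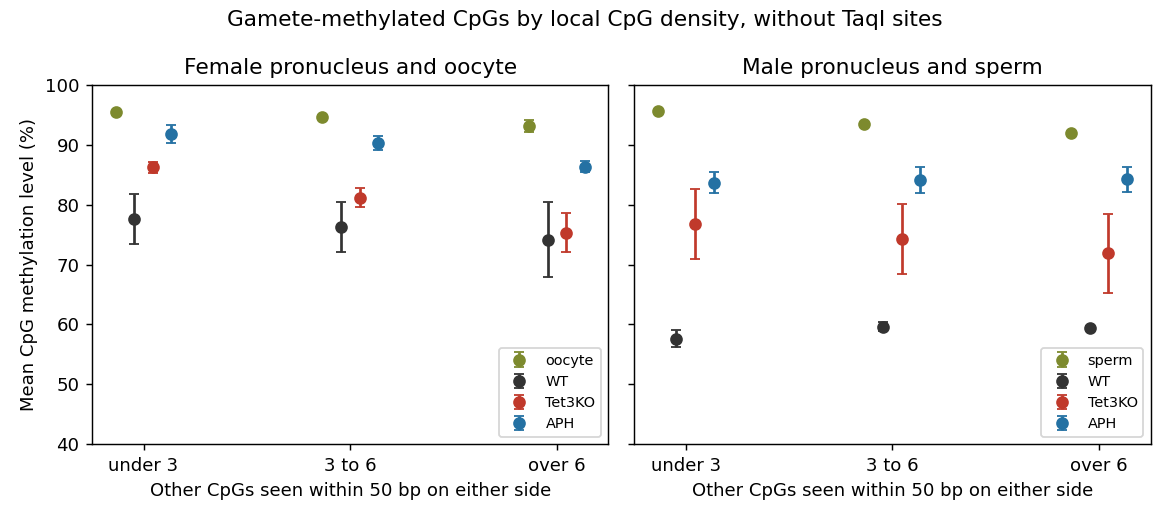
Mean methylation level (%) at gamete-methylated CpGs without TaqI sites, by the number of other CpGs seen within 50 bp on either side, with points for group means and bars for the SD (sperm has 1 library and no bar). Tet3-deficient female pronuclei go from 86.2% at the sparsest to 75.3% at the densest CpGs.

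Repeats, gamete class and the X chromosome were described in the same way, also without TaqI sites except on the X. Within soft-masked repeats, sperm-methylated CpGs read 62.0% ± 0.787 in wild-type, 74.7% ± 4.68 in Tet3-deficient and 84.2% ± 1.69 in aphidicolin-treated male pronuclei. Outside repeats the values were 55.6% ± 1.37, 76.2% ± 6.96 and 83.6% ± 2.23. CpGs methylated in oocytes and under 20% in sperm read 72.3% ± 5.09 in wild-type and 72.4% ± 9.37 in Tet3-deficient female pronuclei, and 85.5% ± 0.472 with aphidicolin. The Tet3-deficient libraries were far apart, 79.1% in replicate 4 and 65.8% in replicate 1; the latter and wild-type replicate 1, at 68.6%, are among the libraries doubted above, so the equal means do not show that Tet3 loss had no effect there. CpGs methylated in both gametes read 77.4% ± 4.05, 84.3% ± 0.316 and 91.4% ± 1.45 in the same 3 groups. CpGs methylated in sperm and under 20% in oocytes read 52.5% ± 2.26, 70.2% ± 5.84 and 79.8% ± 1.76 in wild-type, Tet3-deficient and aphidicolin-treated male pronuclei. Oocyte-methylated CpGs of the X chromosome read 94.9% in oocytes, 82.5% ± 2.53 in wild-type, 86.2% ± 1.96 in Tet3-deficient and 91.1% ± 1.32 in aphidicolin-treated female pronuclei. CpGs under 20% in the gamete, TaqI sites included, stayed low in all pronuclei: 1.93% ± 0.210, 2.89% ± 0.738 and 3.56% ± 0.631 in the 3 kinds of male pronuclei, and 3.46% ± 0.975, 5.11% ± 1.09 and 4.72% ± 0.461 in the female ones.

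The parental origin of each library was checked at CpGs methylated in 1 gamete only (80% or more against 5% or less). At oocyte-only CpGs the female pronuclei read 73.5% to 88.6% and the male pronuclei 6.68% to 20.3%, the highest in Tet3-deficient male replicate 1. At sperm-only CpGs the male pronuclei read 51.1% to 81.4% and the female pronuclei 4.02% to 18.0%. Conversion was checked at cytosines followed by C, which read 0.218% ± 0.00662 in wild-type male pronuclei and 0.312% in sperm over the common set. In oocytes the level was 0.512% ± 0.00088, and in wild-type, Tet3-deficient and aphidicolin-treated female pronuclei 0.494% ± 0.0560, 0.688% ± 0.270 and 0.542% ± 0.0169. The highest library was Tet3-deficient female replicate 4, at 0.878%.

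**Figure D4:**
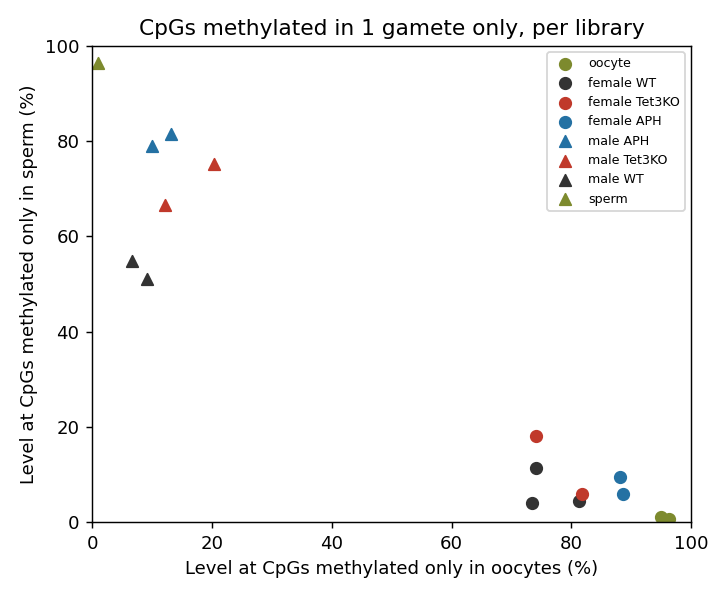
Level (%) at CpGs methylated only in oocytes (x axis) and only in sperm (y axis), one point per library. Tet3-deficient female replicate 1 reads 18.0% and wild-type female replicate 1 reads 11.5% at sperm-only CpGs, above the other female pronuclei at 4.02% to 9.54%.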

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

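The differences of effect between the pronuclei were tests fixed before the data were examined; of the tests of explanations below, those on sperm-only CpGs within male pronuclei and on starting molecules were chosen before their result was seen, and all others, with the ratio of levels at sperm-only CpGs and the strand ratios of other pairs, after it.

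The effect of Tet3 loss differed between male and female pronuclei at 62 tiles, and that of aphidicolin at 61. Both counts are listed because the size of an effect differed between groups, and both moved with single libraries. The test was on the logit scale, while larger and smaller are read in percentage points. For Tet3 the count was 35 without wild-type female replicate 2, 11 without Tet3-deficient female replicate 4, 140 and 131 without wild-type male replicates 2 and 3, and 110 and 173 without Tet3-deficient male replicates 1 and 3. For aphidicolin it was 39, 33 and 110 without wild-type female replicates 1, 2 and 3, 200 and 14 without aphidicolin-treated female replicates 2 and 3, 200 and 170 without wild-type male replicates 2 and 3, and 96 and 123 without aphidicolin-treated male replicates 1 and 2. For Tet3, 47 of the 62 effects were larger in the male pronucleus and 15 smaller; these were 63 and 47 without Tet3-deficient male replicate 1. A linear model (limma) on the percentage-point scale, which changes both the scale and the test, gave counts of 215 and 1434.

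Chromosome Y is absent from oocytes, and CpGs placed on it there, 342 and 356 ppm of all CpGs covered, give the level of misplaced reads. In 3 libraries of female pronuclei the number was above that level: 379 ppm in aphidicolin-treated replicate 2, 522 in Tet3-deficient replicate 1 and 410 in wild-type replicate 1. These are signals outside the comparisons, and their difference from oocytes was not tested. Male pronuclei had 649 to 819 ppm and sperm 916. By share of calls, wild-type female replicate 1 lay below the oocytes. It had 1218 chromosome Y calls beside 25512540 autosomal ones, against 2224 beside 39558166 and 2077 beside 37893814. Wild-type female replicate 2, with 1707 beside 27241052, and Tet3-deficient female replicate 1, with 2246 beside 27996687, lay above them. Aphidicolin-treated female replicate 2, with 1554 beside 27087942, also lay slightly above the oocytes. Which wild-type library stands out therefore depends on the measure.

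CpGs methylated only in sperm read higher in wild-type female replicate 1 (11.5%) and Tet3-deficient female replicate 1 (18.0%) than in the other 5 female libraries (4.02% to 9.54%). DNA from male pronuclei or sperm could add these calls, and sperm-only CpGs at 80% or more in male pronuclei exceeded those under 20% there by 7.38 points in the first library (highest other 5.65) and 11.7 points in the second (highest other 6.58). That leaves the explanation open, because CpGs under 20% in male pronuclei also read 9.21% and 11.02%, and the ratios of the 2 levels, 1.801 and 2.06, were below the highest of the other libraries, 2.22 and 6.35. Chromosome Y positions leave it open too over the 7 female libraries (Spearman rho 0.643, exact permutation p = 0.139, adjusted 0.139; Pearson r 0.917, exact permutation p = 0.00873, adjusted 0.0175), because r rests on those 2 libraries and is 0.545 (exact permutation p = 0.375) without them. Incomplete conversion is not a sufficient cause, as the CC level was raised by only 0.0169 points where 5.56 were needed, while a part played by loss of Tet3 stays open, since the 5.43 points by which the wild-type library lay above the lowest Tet3-deficient one restate the pattern. In the sample list these 2 libraries stand in a separate run of sample numbers with all male pronuclei and sperm. The other 5 female libraries and the oocytes stand in an earlier run. Whether the runs mark batches is not given in the labels, and a batch effect was not tested. Comparisons of male with female pronuclei largely follow the same split.

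CpGs in TaqI sites read above 95% in every library, sperm and oocyte alike. If calls at the end of a digested fragment do not report the sampled DNA, such CpGs should read high even beside unmethylated ones, and at sites whose neighbour within 40 bp was under 20% the lowest of the 16 libraries read 82.8%. Other CpGs in CGA sequence beside an unmethylated neighbour read at most 5.59%, so the sequence alone does not account for it. A preference for keeping reads with an unconverted end could have the same effect and was not tested.

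The 2 wild-type male libraries differed by 1.91 times binomial sampling, against 7.34 to 12.4 in the other 8 pairs of replicates, and shared 80.7% of their CpGs against 37.5% to 65.7%. They are not the same library deposited under 2 names, since even the most alike autosome gave 1.78 times binomial sampling. Shared starting molecules may explain it: strands within a library, which are separate molecules, differed 4.16 times as much as the libraries did, against 0.786 to 1.76 in the other 8 pairs, although a small difference between libraries, which is the pattern itself, also raises this ratio. More starting molecules in both libraries would make their strands more alike too. Their strands differed by 7.91 and 8.57 times binomial sampling, within the range of the other libraries (lowest 1.59, in sperm, median 13.2). Among the other pronuclei only wild-type female replicate 1, at 7.10, and Tet3-deficient female replicate 1, at 8.42, lay below 8.57. By the rule set before the result was seen, these strand values do not decide. The Tet3-deficient female libraries, with strands at 8.42 and 9.53, differed from each other by 7.11, against 1.90 in this pair on such CpGs. That 1 other pair argues against more molecules as the whole cause, while a part in it remains possible. If the molecules are shared, the SD of wild-type male pronuclei may be too small and counts of tiles called against them too large.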

How the results depend on the processing

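Alternatives named here as added were chosen after the data were seen. Of 511 values, 36 are the reported ones, 337 stayed the same, 123 moved, 11 lost their p below 0.05 and 4 changed sign. Counts of called tiles often moved (107 moved, 93 the same). Mean levels at gamete-methylated CpGs kept their direction throughout. Of these, 112 were labelled the same and 6 moved, all 6 for sperm against male pronuclei, which have 1 sperm library and no test. In simulated data for Tet3 loss in females, at the real depths and library numbers, 7 of 70 tiles changed by 80 points were called with the larger assumed spread between replicates and 70 of 70 with the smaller. An uncalled tile is therefore not shown to be unchanged. Nor does a count at an unadjusted p below 0.05 show change by itself. With the larger assumed spread, 7.87% of unchanged simulated tiles in that comparison had such a p. Thinned calls, below, lower the depth of the 2 groups compared only. The dispersion still came from all groups with more than 1 library, the others at full depth. Counts with thinned calls therefore do not measure the effect of depth alone. The causes of the moves were not tested.

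Leaving out 1 library at a time gave these ranges of called tiles: oocytes against female wild type 0 to 106, sperm against male wild type 0 in both cases, Tet3 loss in female 0 to 35 and in male pronuclei 1 to 875, aphidicolin in female 2 to 1662 and in male 0 to 3279, Tet3 loss against aphidicolin in female 6 to 632 and in male 4 to 502, male against female wild type 4998 to 10522, oocytes against sperm 21252 to 21993, and differences of effect 11 to 173 for Tet3 and 14 to 200 for aphidicolin. Mean excesses over both pronuclei ranged from 5.83 to 8.33 points for Tet3 loss and from 11.3 to 12.7 for aphidicolin. The difference between male and female wild type over all CpGs ranged from -0.0962 to 1.92 points, and that of CHH between oocytes and female wild type from -0.0469 to 0.646; both changed sign without wild-type female replicate 3. Cytosines followed by C gave -0.0126 points in place of 0.427 for all non-CpG cytosines (added).

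From 1 call per tile, tiles called were 68 for oocytes against female wild type, 3851 for sperm against male wild type and 107 for Tet3 loss against aphidicolin in males. With 1000-bp tiles these were 172, 6462 and 106, and 1553 for Tet3 loss in males. edgeR called 2286, 60318 and 541 in the same 3 comparisons, 9200 for Tet3 loss in males, 16280 for aphidicolin in males and 425 for Tet3 loss against aphidicolin in females.

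With the dispersion of the 2 groups compared only, the limma-moderated test called 0 tiles for oocytes against female wild type (6229 at an unadjusted p below 0.05), 0 for Tet3 loss in females (3875) and in males (18863), 0 for aphidicolin in females (5806), and 0 for Tet3 loss against aphidicolin in females (5100) and males (5694). It called 49484 for sperm against male wild type and 6454 for aphidicolin in males, where the dispersion comes from the wild-type male pair, alone or with the aphidicolin-treated pair.

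With calls thinned to the lowest library, the limma-moderated test called 0 tiles for oocytes against female wild type (2811 at an unadjusted p below 0.05), 28 for sperm against male wild type, 2 and 85 for Tet3 loss in females and males, 4 and 187 for aphidicolin, 3 and 8 between Tet3 loss and aphidicolin, 3740 for male against female wild type and 22297 for oocytes against sperm.

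With the replicate block, the limma-moderated test called 0 tiles for oocytes against female wild type (5730 at an unadjusted p below 0.05), 0 for aphidicolin in females (6916) and 0 for male against female wild type (13007). The block fit also took the dispersion from the compared libraries only, with few residual degrees of freedom. Without a block, that choice of dispersion already gave 0 in the first 2 of these comparisons, so these counts do not show an effect of the block. Mean differences with the block were 3.59, 5.55 and 1.92 points over all CpGs and 9.09, 8.84 and -10.9 at gamete-methylated CpGs, and it changed no other call. Deviations of equally numbered libraries correlated at -0.0467 to 0.0252, which shows no pairing by number. It cannot exclude pairing, because libraries of a group differ by more than binomial sampling, which can hide shared deviations. Treated male and treated female libraries with the same number were not compared in this way. No paired analysis was possible for the other groups because they share fewer than 2 numbers.

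A linear model on tile levels (added) called 84 for oocytes against female wild type, 11318 for sperm against male wild type, 52 and 5066 for Tet3 loss in females and males, 84 and 9307 for aphidicolin, and 109 and 577 between Tet3 loss and aphidicolin. With at most 130 calls per CpG (added), the limma-moderated test called 0 for oocytes against female wild type (6937 at an unadjusted p below 0.05), 4486 for sperm against male wild type, 2 for Tet3 loss and 13 for aphidicolin in females, and 14 and 28 between Tet3 loss and aphidicolin in females and males.

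Without wild-type female 1, Tet3-deficient female 1 and Tet3-deficient male 1 (added), tiles called were 135 for oocytes against female wild type, 4 and 2 for Tet3 loss in females and males, 616 for aphidicolin in females, 28 and 137 between Tet3 loss and aphidicolin, and 108 and 39 for differences of effect. Mean excesses over both pronuclei were then 6.22 and 12.3 points. With the wild-type male libraries counted as 1 (added), tiles called were 51 against sperm, 295 for Tet3 loss and 1121 for aphidicolin. With a linear model on the percentage-point scale, differences of effect numbered 215 and 1434.

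Without TaqI sites (added), 2985 tiles were called for sperm against male wild type and 135 for the difference of the Tet3 effect, and mean differences were 20.8 points for sperm against male wild type, 34.5 at sperm-methylated CpGs and -21.7 for oocytes against sperm. These 3 differences were 15.7, 22.3 and -18.1 from 10 calls per CpG, 13.98, 19.2 and -16.0 from 1 call, and 29.2, 32.0001 and -27.0 with all calls pooled. Over each library's own CpGs the first and last were 20.9 and -22.0, and Tet3 loss against aphidicolin in females was 0.0529. From 1 call the mean excess with Tet3 loss was 5.65 points. At CpGs methylated in both gametes (added) sperm exceeded male wild type by 17.9 points, and by 32.3 without TaqI sites.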

Other observations

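No test was chosen for the values in this part; they describe libraries and were chosen after the data were seen.

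Over 66496 CpGs covered in all 16 libraries, which put both parental genomes on the same CpGs, sperm read 58.8% and wild-type male pronuclei 39.6% ± 0.422 (n = 2), while oocytes read 43.9% ± 0.199 (n = 2) and wild-type female pronuclei 38.4% ± 1.63 (n = 3). On these CpGs Tet3-deficient pronuclei read 48.8% ± 3.73 in the male and 41.3% ± 0.396 in the female, and aphidicolin-treated ones 53.6% ± 1.53 and 43.7% ± 0.761. CpGs at 20% to 70% in sperm read 48.7% there, 34.4% ± 0.0718 in wild-type, 42.2% ± 3.89 in Tet3-deficient and 48.3% ± 1.103 in aphidicolin-treated male pronuclei. In female libraries, CpGs at 20% to 70% in oocytes read 42.5% ± 0.159 there, 35.8% ± 3.14 in wild-type, 39.0% ± 4.72 in Tet3-deficient and 43.8% ± 1.56 in aphidicolin-treated pronuclei. Tet3-deficient replicate 1, at 35.7%, lay below wild-type replicates 1 and 2, at 38.3% and 36.8%.

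On the X chromosome, which in male pronuclei comes from X-bearing sperm, sperm-methylated CpGs read 92.7% in sperm, 73.2% ± 0.534 in wild-type, 80.5% ± 2.49 in Tet3-deficient and 88.0% ± 0.111 in aphidicolin-treated male pronuclei. The share of all CpG calls that lay on the X chromosome was 2.27% to 2.92% in male pronuclei and 3.52% to 4.08% in female ones.

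Tet3-deficient female replicate 4 had the highest CA level, 11.5%, and also the highest CC level, 0.878%, of all libraries in the common set. Tet3-deficient male replicate 1 read 20.3% at oocyte-only CpGs, against 6.68% to 13.2% in the other male pronuclei. No explanation of these values was tested.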
